A study of Homo sapiens with 22 samples.

How the data were processed

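Gene expression was measured in LNCaP cells on 22 Affymetrix U133A arrays, hybridized with biotin-labelled cRNA. The 11 groups of 2 arrays were untreated cells, vehicle at 8 h and 24 h, and DHT (1 nM) and CPA (10 µM) at 2, 4, 8 and 24 h. The values are intensity as deposited by the authors, who normalized the expression files across the arrays and filtered out genes expressed below 10. The sources used here do not state the normalization method or the summarization software. Checked on the values, the intensities are whole numbers on a linear scale from 13 to 15613, and they are not set relative to the control samples. Raw intensities were not used here, so the probe level was not analysed here, and the number of arrays limits the precision.

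Of 22215 probe sets, the probe annotation used here lists 20108, of which 19065 name a single gene and 1043 several. The 2107 probe sets it does not list and the 1043 with several genes, 3150 in all, were kept out of the gene tests. Gene names follow the annotation of GRCh38.p14, which was used for names only, and 19053 probe sets matched a gene of that annotation. Where several probe sets named a gene (4310 genes), the one with the highest mean log2 intensity stood for it, which left 11963 genes. Intensities were set to a floor of 10 and log2 transformed, and a filter asked for 10 or more on at least 2 arrays. Neither step changed a value or removed a probe set.

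The arrays were fitted together in limma 3.58.1 (R 4.3.3) with a mean for each of the 11 groups, which left 11 residual degrees of freedom, and empirical Bayes with an intensity trend (8.1 prior degrees of freedom). Each compound and time was compared with the mean of the 3 control group means, since the submitters took the average of untreated and vehicle samples as their reference. DHT was compared with CPA at each time, the control groups with each other, and each compound's effect at 24 h with that at 8 h, each against the vehicle of its own time. Tests were two-sided, with Benjamini-Hochberg adjustment over genes within a comparison and a threshold of adjusted p 0.05. The comparisons, the gene lists, the rule for named genes and the alternatives were set before the data were examined, apart from those named as chosen later.

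The rule names, for each compound and time, the 5 genes with the largest change each way among those past the threshold whose treated arrays both lie outside the range of the 6 control arrays. For DHT against CPA it names the 5 each way whose DHT and CPA arrays do not overlap, for the control groups the 3 each way past the threshold, and for each list described the 2 to 4 members with the smallest p. Members that moved against a list's name are named as well, and 6 genes are always named. Of these, 2 of the 6 genes the rule always names had no probe set named in the table used here. Parts of the rule other than the lists named 56 genes, and in 132 pairs of gene and comparison 64 had several probe sets, of which 0 had another past the threshold in the opposite direction.

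The 24 gene lists covered androgen-induced and androgen-repressed genes, glucocorticoid receptor, progesterone receptor, aryl hydrocarbon receptor, PXR and CAR, and p53 targets, G1/S and G2/M genes, cholesterol and fatty acid synthesis, polyamine metabolism, ribosome biogenesis, heat shock, the unfolded protein response, the amino acid response, hypoxia and glycolysis, interferon response and immediate early genes. They also held markers of basal epithelial, neuroendocrine, stromal and immune cells and markers of androgen-insensitive prostate lines. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists and comparisons of a family, then with an estimated correlation and with fry. Against the controls 65 of 192 list tests passed, 18 of them also with an estimated correlation, and for DHT against CPA 29 of 96 passed, 4 of them also with an estimated correlation. The text describes each of these 18 and 4, and some of those that passed with the preset correlation alone. Lists share members: glucocorticoid and progesterone receptor targets share 4 genes, and androgen-induced genes and glucocorticoid receptor targets share 2.

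Fold changes of DHT and CPA share their control arrays, so their correlation was set against 1000 simulated draws of unchanged groups and against separate controls for each compound. Each draw took residuals of groups at random, treated groups included, with random signs. Of these, 6 served as controls shared by both simulated compounds. The draws thus copy the sharing of controls and not the 6 control arrays themselves. The overlap of DHT and CPA calls was set against the overlap of independent lists. Added after the data were seen, it was also set against lists of the same lengths from the simulated draws and against calls made with separate controls. The pipeline was tested on simulated data with 200 changed genes per comparison: at a 1.5-fold change limma recovered 95.5% of changed genes for CPA at 24 h, 94.0% for DHT at 8 h and 82.1% for DHT against CPA at 24 h, and 100% at a 2-fold change, with 4.8%, 3.4% and 6.0% of calls false. Of the simulated lists the 1 changed list was called and 0 of 20 unchanged ones. The simulated genes varied independently of each other, each with 1 spread for all groups. Within the measured lists the estimated correlation reached 0.363, for heat shock. The simulated shares of false calls and the list result need therefore not hold for the measured data.

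The alternatives were a stricter filter (mean intensity of 50), no filter, a pseudocount of 16, quantile normalization, median scaling, the mean of a gene's probe sets, each probe set alone, no intensity trend, the replicate number as a block, other controls, fits of the compared groups alone, a 2-fold minimum and leaving out each array in turn. Without 1 array of a group the remaining array was assumed to vary like the other groups. Leaving out untreated array 2, CPA 2 h array 2 and DHT 8 h array 1 together was added after the data were seen. Comparisons that hold none of these arrays, such as DHT against CPA at 4 h and 24 h, then keep their fold changes. Their counts move only with the estimate of spread shared by all groups and its degrees of freedom. Tables were prepared in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures in matplotlib 3.10.9.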

Results

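The series measured messenger RNA in LNCaP, an androgen-responsive human prostate cancer cell line, on 22 Affymetrix U133A arrays. Cells were kept for 2 days in medium with 5% serum stripped of steroids. They were then left untreated, given the ethanol vehicle for 8 h or 24 h, or treated for 2, 4, 8 or 24 h with 1 nM of dihydrotestosterone (DHT), the main androgen of the prostate, or with 10 µM of cyproterone acetate (CPA), a steroid used clinically as an antiandrogen. That gave 11 groups of 2 arrays each. The labels call the arrays of a group repeats without saying whether they came from separate cultures, so p-values measure only the spread between arrays, which may be technical. The mean intensity per array lay between 234.0 and 283.0, and the number of arrays limits the precision. Fold changes below compare a treated group with the mean of the 3 control groups, which is the reference the submitters' design names, for 11963 genes.

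After 24 h with vehicle, compared with untreated cells, NUSAP1, a spindle protein, fell by 0.93 on the log2 scale (SE 0.15, adjusted p = 1.41e-02), KIF20A, a mitotic kinesin, fell by 0.89 (SE 0.15, adjusted p = 1.42e-02) and PEG3, an imprinted zinc finger gene, fell by 0.90 (SE 0.13, adjusted p = 1.15e-02). With limma, 11 genes passed the threshold, 0 higher and 11 lower. None passed between vehicle at 8 h and untreated cells (1866 genes at an unadjusted p under 0.05) or between the vehicle times (624 genes). Leaving out untreated array 1 raised the first of these counts to 555 and the second to 1039, and the 11 calls went to 0 without untreated array 2 or either vehicle array at 24 h.

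After 2 h of DHT, C1orf116, an androgen-responsive gene of epithelial cells, was 2.22-fold higher than the controls (log2 1.15, SE 0.10, adjusted p = 5.20e-06, n = 2 against 6). ZBTB16, a zinc finger repressor, was 2.04-fold higher (log2 1.03, SE 0.11), and NFKBIA, the inhibitor of NF-kappa-B, was 1.75-fold higher (log2 0.81, SE 0.12). PPP3R1 (log2 0.87) and SET (log2 0.91) were also higher, while TBL1XR1 fell by 1.07, H4C8 by 0.83, PICALM by 0.72, ZNF322 by 0.72 and BAMBI, a pseudoreceptor of the TGF-beta family, by 0.68. The kallikreins had not changed by the test: KLK3, which encodes prostate-specific antigen, stood at log2 0.07 (95% interval -0.41 to 0.55) and KLK2 at log2 0.07 (-0.43 to 0.58). TMPRSS2, a serine protease, was at log2 0.76 (0.23 to 1.29, adjusted p = 0.156) and FKBP5, a co-chaperone of steroid receptors, at log2 -0.01 (-0.45 to 0.42). Of the 14 measured glucocorticoid receptor targets, 4 rose, 1 fell (TSC22D3, log2 -0.55) and 9 did not pass, against 5 higher and 2 lower adjusted over the list alone. The list's camera test was past the threshold (adjusted p = 0.0343; adjusted p = 0.41 with an estimated correlation), with a mean log2 of 0.16 and a median of 0.01, and that call was lost without untreated array 1, either DHT 2 h array, vehicle 8 h array 2 or vehicle 24 h array 1. Of 27 G1/S genes and 31 G2/M genes 0 passed, with 10 higher and 1 lower and 4 higher adjusted over each list alone. Both lists stood higher by camera, with mean log2 of 0.12 and 0.14 (camera adjusted p = 3.02e-04 and 7.16e-05; adjusted p = 0.35 and 0.18 with an estimated correlation). Against the untreated group alone their means were -0.04 and -0.05 and both calls were lost. In all, 45 genes were higher and 25 lower at adjusted p 0.05. The total of 70 became 5 or 3 without DHT 2 h array 1 or 2, and 529 without untreated array 2. It was 39 or 27 without vehicle 8 h array 1 or 2, 32 without vehicle 24 h array 1, 131 after quantile normalization, 1104 without untreated array 2, CPA 2 h array 2 and DHT 8 h array 1 together (a set chosen after the data were seen). Against the untreated group alone it was 3, and there the calls of SET, PPP3R1, NFKBIA, TBL1XR1, H4C8, ZNF322, PICALM and BAMBI were lost.

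After 4 h of DHT, TMPRSS2 was 5.69-fold higher than the controls (log2 2.51, SE 0.25, adjusted p = 2.42e-05), ZBTB16 was 3.33-fold higher (log2 1.74, SE 0.11, adjusted p = 4.30e-08) and C1orf116 was 2.59-fold higher (log2 1.37, SE 0.10). PMEPA1, an androgen- and TGF-beta-responsive membrane protein, was higher by log2 1.2 (SE 0.17), KLK2 by 1.09 (SE 0.24) and FKBP5 by 1.00 (SE 0.21), while KLK3 stood at log2 0.94 (0.45 to 1.42, adjusted p = 0.0637). Of 39 measured androgen-induced genes, 8 rose, 1 fell (BAMBI, log2 -0.91) and 30 did not pass, with 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.49e-10; adjusted p = 0.18 with an estimated correlation). Heat shock genes went the other way: 3 of 10 fell and 7 did not pass, with 5 lower adjusted over the list alone (camera adjusted p = 1.99e-06; adjusted p = 0.14 with an estimated correlation). They were the chaperone cofactors CHORDC1 (log2 -1.13), HSPH1 (log2 -0.73) and DNAJA1 (log2 -0.60). At 2, 4, 8 and 24 h the list's mean log2 was -0.15, -0.39, -0.16 and 0.05 under DHT. Under CPA it was -0.39, -0.32, -0.01 and 0.02. There are no vehicle arrays at 2 h or 4 h, so the lower means there cannot be told from vehicle or handling. Of 24 genes of the unfolded protein response 0 passed, with 1 lower adjusted over the list alone and a mean log2 of -0.15 (camera adjusted p = 2.64e-04; adjusted p = 0.30 with an estimated correlation). TXNIP, an inhibitor of thioredoxin, fell by 0.92, the stress kinase gene EIF2AK3 by 0.92 and the kinase gene SNRK by 0.89. Of the genes past the threshold, 35 were higher and 66 lower. The total of 101 was 11 or 13 without DHT 4 h array 1 or 2, and 219 without untreated array 1. It was 47 without vehicle 8 h array 2, 58 without vehicle 24 h array 2 and 193 against the untreated group alone and 190 without untreated array 2, CPA 2 h array 2 and DHT 8 h array 1 together. The calls of KLK2, FKBP5, CHORDC1 and SNRK were lost without either DHT 4 h array and those of PMEPA1 and EIF2AK3 without array 1, while KLK2, CHORDC1 and FKBP5 also lost theirs without single control arrays.

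After 8 h of DHT, TMPRSS2 was 7.08-fold higher than the controls (log2 2.82, SE 0.25, adjusted p = 3.42e-06) and ZBTB16 3.46-fold higher (log2 1.79, SE 0.11). KLK2 (log2 1.77, SE 0.24), FKBP5 (log2 1.71, SE 0.21) and KLK3 (log2 1.69, SE 0.23) were all higher. These 3 genes differed between the arrays of the group: KLK3 read 563 on the array labelled DHT 8 h replicate 1 and 1593 on replicate 2, KLK2 read 227 and 687, and FKBP5 read 112 and 287. Replicate 1 lay closer to DHT 4 h replicate 2 (SD of the log2 difference 0.078) than to its own group's other array (0.172). Of the 39 androgen-induced genes, 15 rose, 1 fell (BAMBI, log2 -0.79) and 23 did not pass, with 24 higher and 1 lower adjusted over the list alone. The list's call (camera adjusted p = 4.20e-41) held with an estimated correlation (adjusted p = 0.011). INSIG2, a regulator of sterol synthesis, fell by 0.96, SNRK by 0.97, DENND1B by 0.89 and LTN1 by 0.78. In all 62 genes were higher and 46 lower. The total of 108 was 28 without DHT 8 h array 2, where the calls of SNRK, INSIG2, DENND1B and LTN1 were lost, 40 against the 8 h vehicle alone and 194 without untreated array 2, CPA 2 h array 2 and DHT 8 h array 1 together, and DENND1B and LTN1 also lost their calls without single control arrays.

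After 24 h of DHT, KLK3 was 10.4-fold higher than the controls (log2 3.37, SE 0.23, adjusted p = 3.20e-08), at 3102 and 2964 against 253 to 362 on the 6 control arrays. KLK2 was 5.08-fold higher (log2 2.34, SE 0.24). TMPRSS2 was 4.79-fold higher (log2 2.26, SE 0.25). RRM2, a subunit of ribonucleotide reductase, was 3.07-fold higher (log2 1.62, SE 0.09, adjusted p = 1.52e-09) and ATAD2, a chromatin ATPase, 2.84-fold higher (log2 1.51, SE 0.16). TULP4 fell by 0.98, IGFBP3, which binds insulin-like growth factors, by 0.93, DENND1B by 0.93, CD200 by 0.89 and SNRK by 0.88. FKBP5 was at log2 0.84 (0.41 to 1.28, adjusted p = 1.65e-02), a call lost without either DHT 24 h array and against the 24 h vehicle alone, and the call of DENND1B was lost without array 1.

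By list, 25 of the 27 measured G1/S genes rose at 24 h of DHT and 2 did not pass, with 26 higher adjusted over the list alone (camera adjusted p = 7.42e-51). Among them were MCM5 (log2 1.47), a subunit of the replicative helicase, TYMS, thymidylate synthase (log2 1.22), and CDC6, a licensing factor (log2 1.16). Of the 31 G2/M genes, 20 rose and 11 did not pass, with 26 higher adjusted over the list alone (camera adjusted p = 1.45e-24). They included CDK1 (log2 1.31), MAD2L1 (log2 1.41), NUSAP1 (log2 0.91) and TPX2 (log2 0.80). Of the 39 androgen-induced genes, 16 rose and 23 did not pass, with 19 higher adjusted over the list alone (camera adjusted p = 1.23e-18; adjusted p = 0.062 with an estimated correlation). Of the 14 androgen-repressed genes, 6 fell and 8 did not pass, with 7 lower adjusted over the list alone (camera adjusted p = 3.50e-07; adjusted p = 0.062 with an estimated correlation), among them the steroid-conjugating enzymes UGT2B15 (log2 -0.78) and UGT2B28 (log2 -0.59) and DDC, aromatic amino acid decarboxylase (log2 -0.58). Of the 18 cholesterol synthesis genes, 7 rose, 1 fell (TM7SF2, log2 -0.31) and 10 did not pass. There were 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.25e-07). EBP (log2 0.99) and FDPS (log2 0.61) led them. Of 15 ribosome biogenesis genes 5 rose and 10 did not pass, with 6 higher adjusted over the list alone (camera adjusted p = 2.28e-07), led by FBL (log2 0.66) and NOLC1 (log2 0.56). The G1/S, G2/M, cholesterol and ribosome biogenesis calls held with an estimated correlation (camera adjusted p = 0.0062, 0.0073, 0.029 and 0.036). Over all genes, 527 were higher and 260 lower at 24 h of DHT. The total of 787 was 497 or 353 without DHT 24 h array 1 or 2, 432 when the fit held only the groups compared and 1373 without untreated array 2, CPA 2 h array 2 and DHT 8 h array 1 together.

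**Figure D1:**
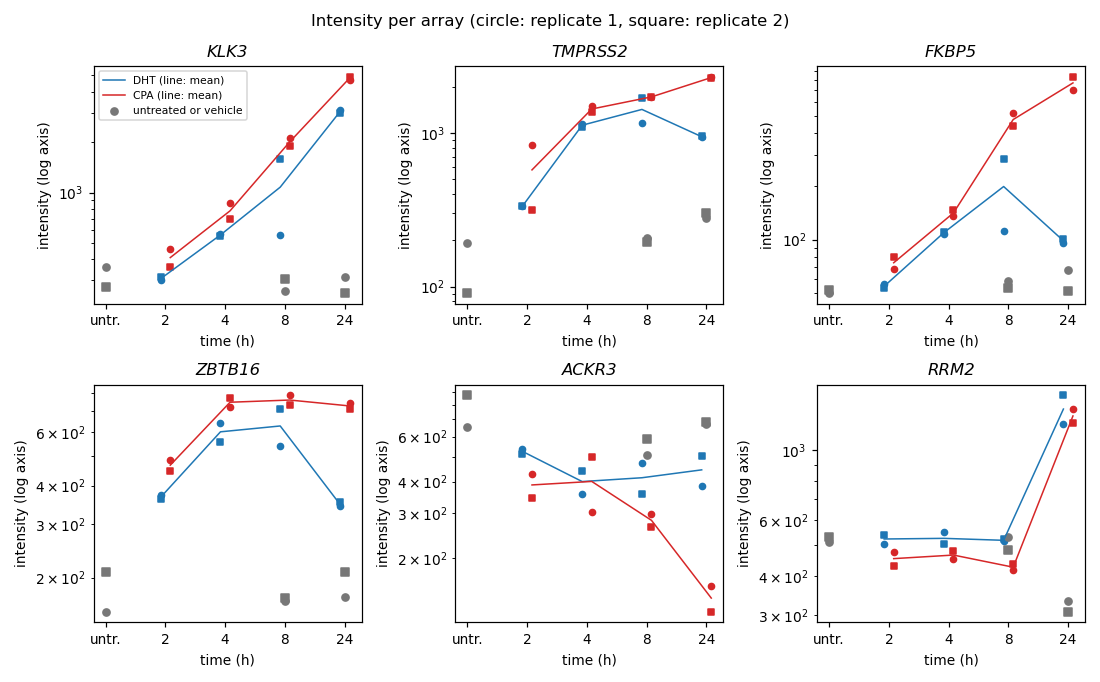
Intensity (log axis) of 6 genes against time on each array: DHT in blue, CPA in red, untreated and vehicle arrays in grey, circles for replicate 1, squares for replicate 2 and lines through the group means of 2 arrays. KLK3 reached 3102 and 2964 at 24 h of DHT and 4706 and 4903 at 24 h of CPA, and the DHT 8 h arrays stood apart at 563 and 1593.

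After 2 h of CPA, TMPRSS2 was 2.60-fold higher than the controls (log2 1.38, SE 0.25, adjusted p = 8.19e-03) and ZBTB16 was 2.60-fold higher (log2 1.38, SE 0.11, adjusted p = 2.44e-06). SGK1, a serum- and glucocorticoid-induced kinase, was higher by log2 1.02 (SE 0.11) and C1orf116 by 0.99 (SE 0.10), with BLM, a DNA helicase, at 0.90 (SE 0.17). BAMBI fell by 1.26 (SE 0.11, adjusted p = 3.01e-06), EIF2S3 by 0.98, ZFP36L1, an RNA decay factor, by 0.96, RB1CC1 by 0.90 and SNRK by 0.90. KLK3 was at log2 0.48 (-0.01 to 0.96), KLK2 at 0.16 (-0.34 to 0.66) and FKBP5 at 0.43 (-0.01 to 0.86), none past the threshold. Heat shock genes fell, 5 of 10 with 5 not passing and 9 lower adjusted over the list alone (camera adjusted p = 0.000415; adjusted p = 0.27 with an estimated correlation), among them DNAJB1 (log2 -0.66) and DNAJA1 (log2 -0.57). Of 18 cholesterol synthesis genes 4 fell and 14 did not pass, with 8 lower adjusted over the list alone (mean log2 -0.21, camera adjusted p = 7.55e-03; adjusted p = 0.18 with an estimated correlation). TM7SF2 (log2 -0.35) and NSDHL (log2 -0.42) were among them. Of 11 fatty acid synthesis genes 1 fell, ACSL1 (log2 -0.58), with 2 lower adjusted over the list alone (mean log2 -0.22, camera adjusted p = 1.57e-02; adjusted p = 0.31 with an estimated correlation). Of 24 genes of the unfolded protein response 5 fell and 19 did not pass, with 5 lower adjusted over the list alone (mean log2 -0.18, camera adjusted p = 1.99e-02; adjusted p = 0.52 with an estimated correlation). PDIA4 (log2 -0.44) and PDIA3 (log2 -0.52), protein disulfide isomerases, were among them. These 3 calls were lost after quantile normalization, with means of -0.09, -0.03 and -0.01. The last 2 were also lost without CPA 2 h array 2, and that of cholesterol synthesis against the untreated group alone. The calls of these 5 genes were lost without CPA 2 h array 2, those of TM7SF2, PDIA4 and PDIA3 after quantile normalization, and that of NSDHL without vehicle array 2 of either time. The 8 immune cell markers stood higher as a list, with a mean log2 of 0.17, 0 members past the threshold and 2 higher adjusted over the list alone (camera adjusted p = 0.0199; adjusted p = 0.37 with an estimated correlation), a call lost without CPA 2 h array 2. In all 388 genes were higher and 949 lower, and after quantile normalization 524 were higher and 336 lower. CPA 2 h array 2 had the lowest mean intensity of the 22 arrays, at 234.0. Without it the total of 1337 was 13 and the calls of BLM, EIF2S3, ZFP36L1, RB1CC1 and SNRK were lost, that of EIF2S3 also without vehicle array 2 of either time. The total was 4018 without CPA 2 h array 1 and 2024 or 868 without untreated array 1 or 2. It was 683 or 371 without vehicle 8 h array 1 or 2, 425 without vehicle 24 h array 2, 22 without untreated array 2, CPA 2 h array 2 and DHT 8 h array 1 together and 5 when only the groups compared were fitted, where TMPRSS2 also lost its call.

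After 4 h of CPA, TMPRSS2 was 7.24-fold higher than the controls (log2 2.86, SE 0.25, adjusted p = 2.13e-06) and ZBTB16 4.17-fold higher (log2 2.06, SE 0.11, adjusted p = 1.99e-09). PMEPA1 was 3.58-fold higher (log2 1.84, SE 0.17), C1orf116 2.99-fold (log2 1.58, SE 0.10) and PNMA1 2.65-fold (log2 1.40, SE 0.15). KLK3 (log2 1.40, SE 0.23), FKBP5 (log2 1.37, SE 0.21) and KLK2 (log2 1.3, SE 0.24) were higher too. BAMBI fell by 1.18, CHORDC1 by 1.10, OSR2 by 0.93, SNRK by 0.79 and INSIG2 by 0.77. Of the 39 androgen-induced genes, 11 rose, 1 fell (BAMBI) and 27 did not pass, with 20 higher and 1 lower adjusted over the list alone. The list's call (camera adjusted p = 2.58e-27) held with an estimated correlation (adjusted p = 0.032). Of the 14 glucocorticoid receptor targets 5 rose and 9 did not pass, with 6 higher and 1 lower adjusted over the list alone. This list's call (camera adjusted p = 4.32e-14, mean log2 0.49, median 0.17) also held with an estimated correlation (adjusted p = 0.0099). Of 10 heat shock genes 3 fell, CHORDC1, HSPH1 (log2 -0.68) and DNAJA1 (log2 -0.61), and 7 did not pass, with 3 lower adjusted over the list alone (camera adjusted p = 1.53e-05; adjusted p = 0.18 with an estimated correlation). In all 55 genes were higher and 37 lower, and 51 and 22 after median scaling. The total of 92 was 34 or 43 without CPA 4 h array 1 or 2 and 184 without untreated array 2, CPA 2 h array 2 and DHT 8 h array 1 together. The calls of KLK3, CHORDC1, SNRK, INSIG2 and the heat shock list were lost without array 1, that of FKBP5 without array 2, that of KLK2 without either and that of CHORDC1 also without single control arrays.

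After 8 h of CPA, TMPRSS2 was 8.69-fold higher than the controls (log2 3.12, SE 0.25, adjusted p = 3.19e-07) and FKBP5 8.66-fold higher (log2 3.11, SE 0.21, adjusted p = 2.96e-08). KLK2 was 6.96-fold higher (log2 2.80, SE 0.24), KLK3 6.84-fold (log2 2.77, SE 0.23) and PMEPA1 5.25-fold (log2 2.39, SE 0.17). LTN1, a ubiquitin ligase of stalled ribosomes, fell by 1.55, DENND1B by 1.33, INSIG2 by 1.25, SNRK by 1.23 and ACKR3, an atypical chemokine receptor, by 1.22. Of the 39 androgen-induced genes, 24 rose, 1 fell (BAMBI, log2 -1.11) and 14 did not pass, with 29 higher and 1 lower adjusted over the list alone (camera adjusted p = 5.88e-51). Of the 14 androgen-repressed genes, 9 fell and 5 did not pass, with 1 higher and 10 lower adjusted over the list alone (camera adjusted p = 8.40e-12). UGT2B28 (log2 -0.65), DDC (log2 -0.53) and BCHE, butyrylcholinesterase (log2 -0.85), were among them. Both calls held with an estimated correlation (camera adjusted p = 0.0073 for the androgen-induced and 0.025 for the androgen-repressed list). In all 139 genes were higher and 201 lower. The total of 340 was 129 or 124 without CPA 8 h array 1 or 2, 530 without untreated array 1 and 154 against the 8 h vehicle alone.

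After 24 h of CPA, KLK3 was 16.4-fold higher than the controls (log2 4.04, SE 0.23, adjusted p = 3.88e-10), FKBP5 13.9-fold (log2 3.80, SE 0.21, adjusted p = 2.36e-10), KLK2 11.8-fold (log2 3.56, SE 0.24) and TMPRSS2 11.6-fold (log2 3.54, SE 0.25). CENPN, a centromere protein, was 7.25-fold higher (log2 2.86, SE 0.15). ACKR3 was 4.70-fold lower (log2 -2.23, SE 0.17, adjusted p = 1.31e-08), DENND1B 3.67-fold (log2 -1.88), CAMK2N1, an inhibitor of CaM kinase, 3.58-fold (log2 -1.84), DDC 3.50-fold (log2 -1.81) and GRB10, a growth factor receptor adaptor, 3.36-fold (log2 -1.75). Over all genes 907 were higher and 912 lower, and after median scaling 1153 and 573. The total of 1819 was 753 without CPA 24 h array 1.

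By list, 32 of the 39 androgen-induced genes rose at 24 h of CPA, 1 fell (BAMBI, log2 -0.86) and 6 did not pass, with 34 higher and 1 lower adjusted over the list alone (camera adjusted p = 5.47e-47). Of the 14 androgen-repressed genes 11 fell and 3 did not pass, with 11 lower adjusted over the list alone (camera adjusted p = 2.91e-14), UGT2B15 among them (log2 -1.71). Of 27 G1/S genes 24 rose and 3 did not pass, with 26 higher adjusted over the list alone (camera adjusted p = 1.94e-36), led by RRM2 (log2 1.55), CDC6 (log2 1.49) and MCM5 (log2 1.40). Of 31 G2/M genes 15 rose and 16 did not pass, with 17 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.49e-10). CDK1 (log2 1.22) and TTK (log2 0.73) led them. Of 18 cholesterol synthesis genes 12 rose and 6 did not pass, with 13 higher and 2 lower adjusted over the list alone (camera adjusted p = 7.44e-14), among them EBP (log2 1.17), INSIG1 (log2 1.16) and IDI1 (log2 0.85). Of 11 fatty acid synthesis genes 7 rose and 4 did not pass, with 8 higher adjusted over the list alone (camera adjusted p = 2.39e-07), among them the elongase ELOVL5 (log2 1.67), fatty acid synthase FASN (log2 1.02) and the carboxylase ACACA (log2 0.63). All 6 of these list calls held with an estimated correlation. In the order given, their camera adjusted p was then 0.0088, 0.013, 0.0073, 0.045, 0.0073 and 0.043. Of 10 polyamine genes 4 rose and 6 did not pass, with 5 higher adjusted over the list alone (camera adjusted p = 3.06e-05; adjusted p = 0.18 with an estimated correlation), SMS, spermine synthase, at log2 1.88 and ODC1, ornithine decarboxylase, at 0.66. Of 24 genes of the unfolded protein response 8 rose, 1 fell (DDIT3, log2 -0.50) and 15 did not pass, with 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 7.02e-05; adjusted p = 0.26 with an estimated correlation), SSR1 at log2 0.71 and CRELD2 at 0.56. Of 13 p53 targets 1 rose (TNFRSF10B, log2 0.43), 4 fell and 8 did not pass, the same numbers as adjusted over the list alone (camera adjusted p = 0.0116; adjusted p = 0.16 with an estimated correlation). SESN1, a stress-induced regulator of growth, fell by 1.23, and CDKN1A, the cell cycle inhibitor p21, by 0.83.

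**Figure D2:**
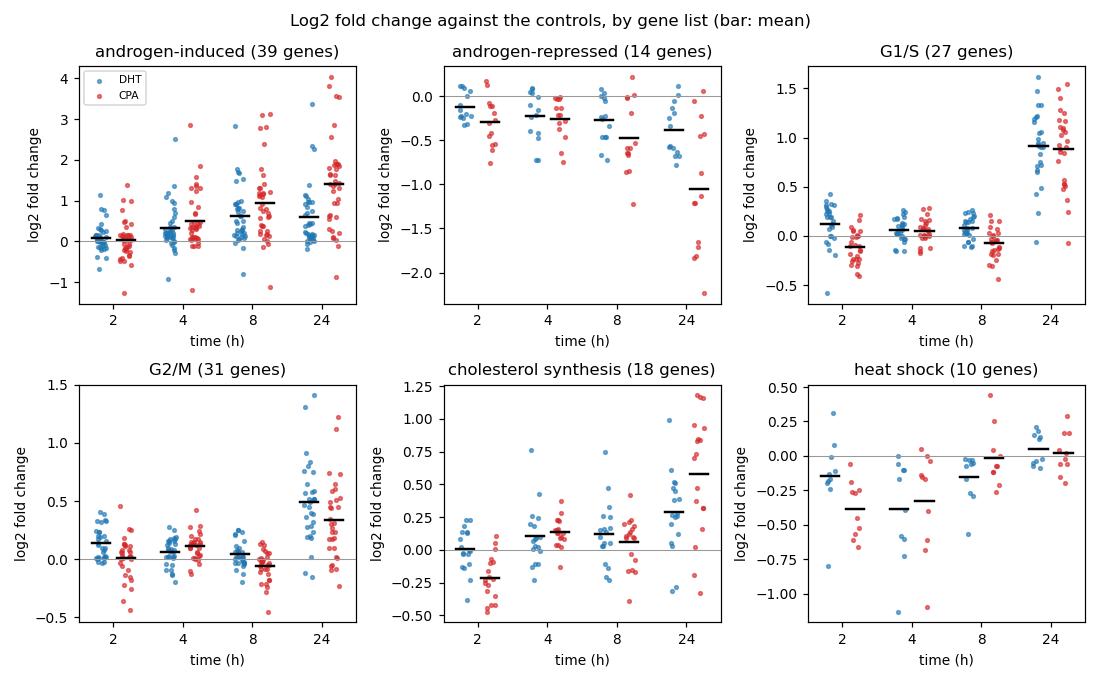
Log2 fold change against the controls (vertical axis) at each time in h (horizontal axis) for the measured members of 6 gene lists, 1 point per gene, DHT in blue and CPA in red, with a black bar at the list's mean. At 24 h the mean of the 39 androgen-induced genes was 0.60 under DHT and 1.42 under CPA, and that of the 27 G1/S genes was 0.91 and 0.89.

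Markers of other cell types were measured as a background for these lists. At 24 h, basal epithelial markers had 1 of 6 members past the threshold under DHT (KRT14, log2 0.24) and 0 under CPA, and immune cell markers and markers of androgen-insensitive prostate lines had 0 of 8 and 0 of 10 under both. Of 12 stromal markers, 0 passed under DHT and 2 fell under CPA, FN1, fibronectin (log2 -0.71), and COL3A1 (log2 -0.43). Of 13 neuroendocrine markers, NTS, neurotensin, fell under both compounds (log2 -0.38 and -0.78) and ENO2 under CPA (log2 -0.58). Adjusted over the list alone, KRT14 and NTS passed under DHT, and NTS, ENO2, 3 stromal markers lower and 1 stromal marker higher under CPA. None of these lists passed camera against the controls at 24 h, at adjusted p between 0.323 and 0.944. By fry, neuroendocrine and stromal markers were lower at 24 h of CPA (adjusted p = 0.0201 and 0.0365). The other marker lists under CPA, and all of them under DHT, did not pass fry. FN1 (log2 0.94) and COL3A1 (log2 0.57) were higher under DHT than under CPA.

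The compounds were compared directly at each time, at doses that differ (1 nM of DHT and 10 µM of CPA). At 24 h FKBP5 was 7.77-fold lower under DHT than under CPA (log2 -2.96, 95% interval -3.49 to -2.43, adjusted p = 1.21e-06). PMEPA1 was 3.74-fold lower (log2 -1.90, -2.33 to -1.47) and LRIG1, an inhibitor of growth factor receptors, 3.61-fold (log2 -1.85, -2.32 to -1.38). Also lower were ORM1, an acute phase protein, 3.50-fold (log2 -1.81, -2.07 to -1.54) and EAF2, an elongation factor partner, 3.19-fold (log2 -1.67, -2.02 to -1.32). ACKR3 was 3.17-fold higher under DHT (log2 1.66, 1.24 to 2.09, adjusted p = 5.48e-05). Also higher were PEG3 2.79-fold (log2 1.48, 1.2 to 1.76), UGT2B17 2.46-fold (log2 1.3, 0.89 to 1.71), DDC 2.34-fold (log2 1.22, 1.05 to 1.40) and BARD1, the partner of BRCA1, 2.30-fold (log2 1.2, 0.93 to 1.48). TMPRSS2 (log2 -1.28, -1.93 to -0.63, adjusted p = 3.67e-02) and KLK2 (log2 -1.22, -1.83 to -0.60, adjusted p = 3.42e-02) were lower under DHT. Both calls were lost without any 1 of the 4 arrays. KLK3 missed the threshold at log2 -0.66 (-1.26 to -0.07, adjusted p = 0.421).

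Of the 39 androgen-induced genes, 21 were lower under DHT than under CPA at 24 h, 1 was higher (BAMBI, log2 0.98) and 17 did not pass, with 30 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.53e-49). SGK1 was among the lower genes (log2 -1.60). Of the 14 androgen-repressed genes 7 were higher under DHT and 7 did not pass, with 10 higher adjusted over the list alone (camera adjusted p = 5.84e-17), CAMK2N1 among them (log2 1.16). Of the 18 cholesterol synthesis genes, 2 were lower, IDI1 (log2 -0.58) and LSS (log2 -0.44), and 16 did not pass, with 7 lower adjusted over the list alone (camera adjusted p = 1.43e-10). Of the 14 glucocorticoid receptor targets 5 were lower and 9 did not pass, with 7 lower adjusted over the list alone (camera adjusted p = 1.90e-09), ZBTB16 (log2 -1.07) and NFKBIA (log2 -0.89) among them, and 2 members, FKBP5 and SGK1, are also on the androgen-induced list. These 4 calls held with an estimated correlation (camera adjusted p = 0.011, 0.011, 0.011 and 0.04, in the order given). The G1/S genes did not differ by the test, with 0 of 27 past the threshold, 1 lower adjusted over the list alone and a mean log2 difference of 0.02 and a median of 0.07 where camera's direction was lower (adjusted p = 0.823). With 1 array left out camera passed in opposite directions: higher under DHT without CPA 24 h array 1 (mean 0.11), and lower without CPA 24 h array 2 (mean -0.07) or DHT 24 h array 2 (mean -0.05). In all 95 genes were higher under DHT and 132 lower, and 66 and 143 after median scaling. The total of 227 was between 95 and 138 without any 1 of the 4 arrays compared, CPA 24 h arrays 1 and 2 and DHT 24 h arrays 1 and 2, 426 without untreated array 2, CPA 2 h array 2 and DHT 8 h array 1 together and 24 when only the groups compared were fitted, where the calls of ACKR3, UGT2B17, BARD1, EAF2 and KLK2 were lost.

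**Figure D3:**
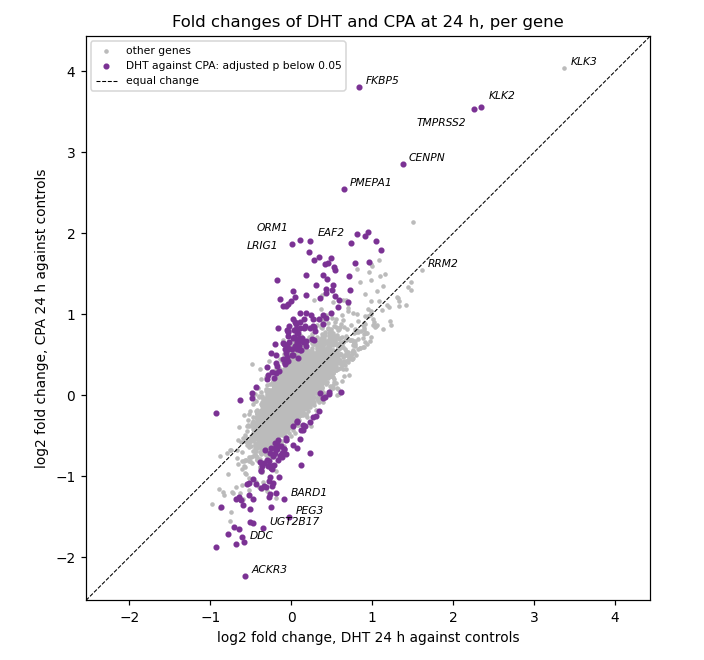
Log2 fold change at 24 h against the controls under DHT (horizontal axis) and CPA (vertical axis), 1 point per gene for 11963 genes, with the 227 genes that passed the direct comparison of DHT and CPA in purple and the line of equal change dashed. FKBP5 lay far above the line, at 0.84 under DHT and 3.80 under CPA, and RRM2 near it, at 1.62 and 1.55.

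At 8 h, PEG3 was 1.85-fold higher under DHT than under CPA (log2 0.89, 0.61 to 1.17, adjusted p = 2.71e-02) and was the 1 gene past the threshold. FKBP5 (log2 -1.41, -1.94 to -0.87, adjusted p = 0.072), KLK3 (log2 -1.08, -1.67 to -0.49), KLK2 (log2 -1.03, -1.65 to -0.42) and TMPRSS2 (log2 -0.30, -0.95 to 0.36) missed it, and these intervals do not show that the compounds acted alike. As a list the 39 androgen-induced genes were lower under DHT, with 0 past the threshold over all genes and 8 lower adjusted over the list alone (mean log2 -0.32, camera adjusted p = 5.94e-17; adjusted p = 0.097 with an estimated correlation). Without the array labelled DHT 8 h replicate 1 that mean was -0.07 and the list's call was lost. The call of PEG3 was lost without DHT 8 h array 1 or either CPA 8 h array, where the count was 0 except without CPA 8 h array 2, and without DHT 8 h array 2 the count was 12, with KLK3, KLK2 and FKBP5 lower under DHT and past the threshold.

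At 4 h, 0 genes passed between the compounds in limma (525 at an unadjusted p under 0.05), and 7 did without untreated array 2, CPA 2 h array 2 and DHT 8 h array 1 together. As lists, the 39 androgen-induced genes and the 14 glucocorticoid receptor targets were lower under DHT, each with 2 lower adjusted over the list alone (mean log2 -0.17 and -0.19, camera adjusted p = 5.69e-05 and 1.18e-05; adjusted p = 0.44 and 0.097 with an estimated correlation). The interval of the difference was -1.0 to 0.30 for TMPRSS2, -1.06 to 0.12 for KLK3, -0.83 to 0.40 for KLK2 and -0.90 to 0.16 for FKBP5, which leaves room for differences of up to log2 -1.06. At 2 h, ATP8B1 (log2 1.26, 0.50 to 2.02), NAA15 (log2 1.03), MTCL2 (log2 1.00), NACC2 (log2 0.93) and ESF1 (log2 0.92) were higher under DHT, and BLM (log2 -0.91), CYP4F12 (log2 -0.83), PRSS50 (log2 -0.78), CBX2 (log2 -0.75) and TG were lower. KLK3 (-1.0 to 0.19), KLK2 (-0.70 to 0.53), TMPRSS2 (-1.27 to 0.03) and FKBP5 (-0.97 to 0.10) did not pass at 2 h. At that time 570 genes were higher and 183 lower under DHT, and 142 and 152 after quantile normalization. The total of 753 was 2895 or 30 without CPA 2 h array 1 or 2, 3 or 0 without DHT 2 h array 1 or 2 and 0 when only the groups compared were fitted, and each of the 10 genes named here lost its call without either DHT 2 h array, all but ATP8B1 without CPA 2 h array 2 and ATP8B1 without CPA 2 h array 1.

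The fold changes of DHT and CPA were also set against each other across all genes, which are not independent replicates. TMPRSS2, ZBTB16, C1orf116 and PMEPA1 rose under both compounds at 4 h, and Pearson's r over 11963 genes was 0.30 at 2 h, 0.62 at 4 h, 0.77 at 8 h and 0.76 at 24 h, with Spearman's rho of 0.20, 0.46, 0.62 and 0.67. Unchanged groups simulated with 6 shared controls, drawn from the residuals of any group, gave a median r of 0.28 (95% of draws -0.18 to 0.66). With separate control arrays for each compound, the 2 ways of giving them out gave r of 0.01 and 0.38 at 2 h, 0.61 and 0.18 at 4 h, 0.52 and 0.56 at 8 h, and 0.66 and 0.63 at 24 h. Their means were 0.20, 0.40, 0.54 and 0.64. The covariance was 0.0106, 0.0129, 0.0196 and 0.0435 against a simulated median of 0.00279, and an upper limit of 95% of draws of 0.0104. Without CPA 2 h array 2, r at 2 h was 0.02, and it was 0.08 without untreated array 2, CPA 2 h array 2 and DHT 8 h array 1 together. Without CPA 4 h array 1, r at 4 h was 0.28, and without DHT 8 h array 2, r at 8 h was 0.56.

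The overlap of calls, which shared controls raise on average with no effect at all, was counted too. Among genes called under both compounds, FKBP5, KLK3, KLK2 and TMPRSS2 were higher at 8 h and 24 h. At 24 h 414 genes were higher under both, where independent lists of 527 and 907 would share 40.0, and 192 were lower under both, where lists of 260 and 912 would share 19.8. Lists of these lengths from unchanged groups, simulated with 6 shared controls in the same way, shared a median of 65 (upper limit of 95% of draws 168) and 33 (92). At 8 h 52 were higher under both (0.7 if independent, simulated 1, limit 5) and 42 lower (0.8, simulated 1, limit 5). At 4 h 29 were higher (0.2, simulated 0, limit 2) and 27 lower (0.2, simulated 0, limit 2). At 2 h 8 were higher (1.5, simulated 2, limit 9) and 13 lower (2, simulated 3, limit 11). With separate control arrays for each compound, in the 2 ways of giving them out, the overlap was 5 or 2 higher and 6 or 1 lower at 2 h, and 16 or 15 higher and 9 or 12 lower at 4 h. It was 37 or 32 higher and 10 or 23 lower at 8 h, and 274 or 237 higher and 66 or 122 lower at 24 h. The simulated and separate-control overlaps were chosen after the data were seen. The independent value leaves out the shared controls and the simulated value the effects. The reference pools untreated and vehicle arrays, and there are no vehicle arrays at 2 h or 4 h. What vehicle or handling did alike under both compounds would therefore stay in these overlaps, also with separate controls.

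The change of each compound's effect between 8 h and 24 h, each time set against the vehicle of that time, was tested as a difference of differences. RRM2, chosen here after its values were seen together with MCM5, had a larger effect at 24 h than at 8 h under both compounds, at log2 2.04 for DHT and 2.26 for CPA, and MCM5 at log2 1.64 and 1.98. For DHT 93 genes had a higher effect at 24 h and 13 a lower one, and for CPA 134 and 47, or 173 and 32 after median scaling. The DHT total of 106 was 60 or 46 without vehicle 8 h array 1 or 2, 61 without either vehicle 24 h array and 190 without untreated array 2, CPA 2 h array 2 and DHT 8 h array 1 together. The CPA total of 181 was 115 or 87 without CPA 8 h array 1 or 2, 114 or 101 without vehicle 8 h array 1 or 2, 103 without CPA 24 h array 1 and 120 without vehicle 24 h array 1. It was 414 without those 3 arrays and 425 when only the groups compared were fitted. None of the 3 arrays is part of the CPA comparison, so its fold changes stayed the same. Only the shared estimate of spread and its degrees of freedom moved.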

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

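The tests of explanations in this part, the difference between the compounds in their change from 8 h to 24 h and the counts of probe sets without a single gene were chosen after the results were seen, while the comparisons of each compound's effect at 24 h with that at 8 h were planned.

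The effect of DHT differed between 24 h and 8 h for 106 genes and that of CPA for 181, by a test of the difference itself. The change from 8 h to 24 h differed between DHT and CPA for 8 genes, with 419 at an unadjusted p under 0.05, and for 22 genes without the array labelled DHT 8 h replicate 1. Among the 3150 probe sets without a single gene name, 120 passed the threshold at 24 h of DHT, 71 of them higher than in the control arrays, and 325 at 24 h of CPA, 143 of them higher. Gaps within groups were not examined for single distant samples, since each group holds 2 arrays.

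The array labelled DHT 8 h replicate 1 lay closer to DHT 4 h replicate 2 than to the other DHT 8 h array. Over 8584 genes called in no compound comparison, the SD of the log2 difference of that pair was 0.0795. The smallest value of any pair within a group was 0.0966, that of the DHT 2 h arrays. The interval of the first value, 0.0781 to 0.081, came from resampling genes and holds no spread between arrays. The pair was noticed as close over all 11963 genes, which include these 8584, so its rank here is no independent test. The next closest pair of different groups had an SD 1.58 times as large (1.55 to 1.61, also from resampling genes). The closeness was thus not confined to genes called as changed. Whether a slower response of an 8 h culture was the source is not decided by this, since the pair was picked for its closeness and uncalled genes may still respond. RNA or a culture shared by both arrays may account for the pattern, and handling shared by them on a given day stays open, since the labels give no dates. The array was kept under its label throughout.

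Counts at 2 h changed several-fold with single arrays, and no biological explanation was tested for this. A compressed intensity range on CPA 2 h array 2 stays open by the bounds set. Quantile normalization gives all arrays 1 range. Of 1337 genes called at 2 h of CPA, 625 (46.7%) were called in the same direction after it. That share is too high to count for compression and too low to count against it. It hides a split by direction: 299 of 388 higher calls were kept, but only 326 of 949 lower calls. The slope of the log2 difference, array 2 minus array 1, on mean log2 was -0.051 for CPA 2 h. In the other groups it ran from -0.027 to 0.038. For the lower calls these values go with compression, while most higher calls did not depend on it. The deviation of untreated array 2 from array 2 of both vehicle groups was set against that of the DHT 2 h arrays from the control arrays numbered 1. With no control array in common, they correlated across genes at r = 0.56, where the highest other group gave 0.25. Untreated array 2 also differs from those vehicle arrays by the vehicle and the time, which this correlation cannot separate. A source shared by untreated array 2 and the DHT 2 h arrays may thus lie behind part of the pattern, and the labels do not say what they share.

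Androgen-induced genes were higher under CPA than under DHT at 24 h. A smaller change of all genes on the DHT 24 h arrays is argued against. The G1/S genes rose under DHT by 1.03 times their rise under CPA, against 0.42 times for the androgen-induced genes. The interval of the first ratio, 0.94 to 1.12, came from resampling the 27 genes and holds no spread between arrays. With single arrays left out, the mean log2 difference of the G1/S genes between DHT and CPA ran from -0.07 to 0.11. That of the androgen-induced genes was -0.82 with all arrays. The changes from 8 h to 24 h that follow compare treated arrays of the 2 times without their vehicle arrays. A change of the culture over time is thus part of each of them, and it cancels only in the difference between the compounds. From 8 h to 24 h the 39 androgen-induced genes had a mean log2 change of -0.02 under DHT (fry adjusted p = 0.78) and 0.48 under CPA (adjusted p = 0.0027), with a difference of -0.50 (adjusted p = 0.015), and without the array labelled DHT 8 h replicate 1 the change under DHT was -0.27 (adjusted p = 0.0021) and the difference -0.75 (adjusted p = 6.8e-06). The 29 genes higher at 4 h under both compounds, which share FKBP5 among others with the 39, had -0.47 under DHT by fry (adjusted p = 2.9e-05) and 0.21 under CPA (adjusted p = 0.028). Without that array the mean change under DHT was -0.57. These genes were picked for high values at 4 h, also on DHT 4 h replicate 2, the array close to DHT 8 h replicate 1. Their fall is thus not separate evidence on the 39. The compounds thus drew apart on the 39 genes with or without that array, while a fall of them under DHT did not pass with all arrays, passed without that one and stays open, as do the dose and the biology of each compound, which differ together in this design and were not tested.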

How the results depend on the processing

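In this part the values without untreated array 2, CPA 2 h array 2 and DHT 8 h array 1 together were chosen after the data were seen, and all others were planned. Of 94 list calls, 22 kept direction and threshold with an estimated correlation, 61 with fry, 79 after quantile normalization, 82 with the mean of a gene's probe sets, 92 after median scaling and 93 with the replicate block, and 54 of 65 against 1 control group alone, the untreated group at 2 h and 4 h, which have no vehicle arrays, and the vehicle of the same time at 8 h and 24 h. Of 111 calls of named genes 110 were kept with the replicate block, 81 when only the groups compared were fitted, 101 with the mean of a gene's probe sets and 104 after median scaling, and none reversed under the alternatives run. The replicate numbers showed no steady pairing of the arrays. Over 55 pairs of groups the correlation of replicate differences ran from -0.43 to 0.59, with a median of 0.01. Deviations from the group mean were also compared between arrays of different groups by correlation. The 2 deviations of a group are opposite in sign, so the highest correlation of an array cannot be below 0. For 14 of 22 arrays the highest of these correlations was with an array of their own number. Both arrays of a group always count alike here, so this holds 1 result per group and does not decide on pairing. Omitting the filter changed nothing, since it removes no probe set, and is no test. Values near the lowest intensities, 13 here, cannot be told from background on these arrays.

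Counts of genes past the threshold that moved by over 1.5 times are given next, and the cause was not tested except where fewer arrays or a stricter threshold is the change itself. With a 2-fold minimum the counts against the controls at 2, 4, 8 and 24 h were 3, 6, 10 and 34 for DHT and 4, 14, 43 and 152 for CPA, those of DHT against CPA 3 at 2 h, 0 at 8 h and 44 at 24 h, vehicle at 24 h against untreated 0, and the effects at 24 h against 8 h 51 for DHT and 79 for CPA. With only the groups compared fitted they were 41, 44 and 432 for DHT at 2, 8 and 24 h, 5 for CPA at 2 h, 0, 0 and 24 for DHT against CPA at 2, 8 and 24 h, 0 for vehicle at 24 h against untreated and 425 for the CPA effect. Without the 3 arrays named above they were 1104, 190, 194 and 1373 for DHT at 2, 4, 8 and 24 h, 22 and 184 for CPA at 2 and 4 h, 7, 0 and 426 for DHT against CPA at 4, 8 and 24 h, 1 and 0 for vehicle at 8 h and 24 h against untreated, 8 between the vehicle times, and 190 and 414 for the DHT and CPA effects. None of these arrays is part of DHT against CPA at 4 h and 24 h, the comparison of the vehicle times or the CPA effect. There the fold changes stayed the same, and only the shared estimate of spread and its degrees of freedom moved. Quantile normalization gave 131 for DHT at 2 h, 860 for CPA at 2 h, 294 and 4 for DHT against CPA at 2 and 8 h and 2 between the vehicle times. Against the untreated group alone they were 3 and 193 for DHT at 2 and 4 h, and against the 8 h vehicle alone 40 for DHT and 154 for CPA at 8 h. Each probe set alone gave 150 for DHT at 2 h and 0 for DHT against CPA at 8 h, the 6 control arrays as 1 group 46 for DHT at 2 h, the mean of probe sets 492 for DHT against CPA at 2 h, and median scaling 0 and the replicate block 2 for DHT against CPA at 8 h.

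Leaving out 1 array at a time gave 3 to 529, 11 to 219, 28 to 162 and 353 to 917 for DHT at 2, 4, 8 and 24 h, and 13 to 4018, 34 to 113, 124 to 530 and 753 to 1985 for CPA. For DHT against CPA it gave 0 to 2895 at 2 h, 0 at 4 h, 0 to 12 at 8 h and 95 to 138 at 24 h. It gave 0 to 1039 and 0 to 555 for vehicle at 8 h and 24 h against untreated, 46 to 112 for the DHT effect and 87 to 179 for the CPA effect. The correlation of DHT and CPA at 8 h ran from 0.56 to 0.81 and was 0.54 as a mean over separate controls.

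Against the untreated group alone the mean log2 reversed from 0.12 to -0.04 for the G1/S and from 0.14 to -0.05 for the G2/M genes at 2 h of DHT, from 0.06 to -0.12 for the G2/M genes at 4 h of DHT (camera adjusted p = 0.0282; adjusted p = 0.49 with an estimated correlation), and from 0.05 to -0.11 for the G1/S (camera adjusted p = 0.0957) and from 0.11 to -0.08 for the G2/M genes at 4 h of CPA (camera adjusted p = 6.61e-05; adjusted p = 0.18 with an estimated correlation). Of the 31 G2/M genes 0 passed at 4 h of either compound. Against the 8 h vehicle alone it reversed from -0.05 to 0.06 for the unfolded protein response at 8 h of DHT (camera adjusted p = 0.366 against the 3 control groups). The heat shock mean at 8 h of DHT was -0.16, with 0 of 10 genes past the threshold (camera adjusted p = 0.0282; adjusted p = 0.51 with an estimated correlation). It ran from -0.31 to -0.00 with 1 array left out, where the direction of its test reversed without DHT 8 h array 1, and was 0.01 without the 3 arrays. The direction of the test of the G1/S genes between DHT and CPA at 24 h reversed without CPA 24 h array 1, with a mean from -0.07 to 0.11 over the arrays left out. The cause was not tested.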

Other observations

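The gene groups in this part belong to lists set before the data were examined, and no test of an explanation is added here.

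At 24 h, of 23 hypoxia and glycolysis genes, 4 rose and 1 fell (BNIP3L, log2 -0.36) under DHT, with 8 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000379; adjusted p = 0.18 with an estimated correlation), and 6 rose and 3 fell (BNIP3L, ENO2 and ADM) under CPA, with 10 and 3 adjusted over the list alone (camera adjusted p = 0.000923; adjusted p = 0.22 with an estimated correlation). The DHT call was lost without DHT 24 h array 2. HK2, hexokinase 2, was at log2 0.51 under DHT and 0.68 under CPA, and LDHA, lactate dehydrogenase, at 0.59 under DHT. Of 10 polyamine genes 4 rose under DHT and 6 were higher adjusted over the list alone (camera adjusted p = 0.000571; adjusted p = 0.28 with an estimated correlation), SRM, spermidine synthase, at log2 0.52. Of 11 fatty acid synthesis genes 2 rose and 1 fell (ME1, log2 -0.36) under DHT, with 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0221; adjusted p = 0.34 with an estimated correlation), ELOVL5 at log2 1.08, and the list's call was lost without DHT 24 h array 2. Of 15 ribosome biogenesis genes 6 rose under CPA and 8 were higher adjusted over the list alone (camera adjusted p = 1.71e-05; adjusted p = 0.062 with an estimated correlation), NOP16 at log2 0.83. Of 23 amino acid response genes 1 fell under DHT and 5 under CPA (camera adjusted p = 0.206 and 0.271), and 1 lower under DHT and 1 higher and 5 lower under CPA adjusted over the list alone. They included SLC7A11, a cystine transporter (log2 -0.61 and -0.91), and ASNS, asparagine synthetase (log2 -0.54 under CPA). Of 18 interferon response genes 1 fell under DHT (MX2, log2 -0.43) and 2 under CPA (IRF9, log2 -0.33, and IFIT2, log2 -0.33), with 3 and 1 lower adjusted over the list alone and camera adjusted p = 0.0525 and 0.0675. By fry the list was lower under CPA (adjusted p = 0.0194) and did not pass under DHT (adjusted p = 0.0855). Of 22 immediate early genes 0 passed under DHT and 2 fell under CPA, DUSP1 (log2 -0.53) and MCL1 (log2 -0.36), as adjusted over the list alone, with camera adjusted p = 0.168 and 0.847. By fry these genes were lower under DHT (adjusted p = 0.0477) and did not pass under CPA (adjusted p = 0.0954). Of 10 heat shock genes 0 passed under either compound at 24 h (camera adjusted p = 0.346 and 0.385).

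Of 14 glucocorticoid receptor targets 5 rose and 1 fell (TSC22D3, log2 -0.67) at 4 h of DHT, the same numbers as adjusted over the list alone (camera adjusted p = 0.000157; adjusted p = 0.13 with an estimated correlation), with a mean log2 of 0.29 and a median of 0.02. At 8 h of DHT 5 rose, with 5 higher and 1 lower adjusted over the list alone, a mean of 0.39 and a median of 0.05. The list's call at 8 h of DHT (camera adjusted p = 1.57e-07) held with an estimated correlation (adjusted p = 0.045). At 24 h of DHT 3 rose (camera adjusted p = 0.641). Of the same targets 6 rose at 8 h of CPA and 6 were higher and 1 lower adjusted over the list alone, with a mean log2 of 0.56 and a median of 0.14. The list's call at 8 h of CPA (camera adjusted p = 2.25e-09) held with an estimated correlation (adjusted p = 0.029). At 24 h of CPA 6 rose and 2 fell, the phosphatase gene DUSP1 (log2 -0.53) and TSC22D3, also known as GILZ (log2 -0.41), the same numbers as adjusted over the list alone (camera adjusted p = 0.000147; adjusted p = 0.13 with an estimated correlation), with a mean of 0.59 and a median of 0.08. CEBPD was at log2 0.95 and SGK1 at 1.42. Of 12 progesterone receptor targets 2 rose and 1 fell (TSC22D3) at 4 h of DHT and 2 rose at 8 h of DHT (camera adjusted p = 0.00343 and 0.00528; adjusted p = 0.069 and 0.081 with an estimated correlation), 2 rose at 4 h and at 8 h of CPA (camera adjusted p = 0.00439 and 0.000264; adjusted p = 0.075 and 0.036 with an estimated correlation), and 3 rose and 2 fell (TSC22D3 and HSD11B2) at 24 h of CPA, the same numbers as adjusted over the list alone (camera adjusted p = 0.0254; adjusted p = 0.16 with an estimated correlation), RGS2 at log2 0.66, and 4 of the list's genes, FKBP5 and ZBTB16 among them, are also glucocorticoid receptor targets. Of 6 aryl hydrocarbon receptor targets 1 rose, TIPARP, at 4 h and 8 h of DHT and at 4 h of CPA, where the list passed (camera adjusted p = 0.00311, 0.036 and 0.0298; adjusted p = 0.053, 0.14 and 0.13 with an estimated correlation). The 8 h call was lost without either untreated array, array 2 of either vehicle group or DHT 8 h array 1, and the CPA call without untreated array 2 or CPA 4 h array 2. TIPARP rose at 24 h of CPA (log2 0.65) and NQO1 fell (log2 -0.26), with camera adjusted p = 0.924, and 0 passed under DHT (camera adjusted p = 0.91). Of 9 PXR and CAR targets 0 passed under DHT or CPA at 24 h (camera adjusted p = 0.759 and 0.594). Of 24 genes of the unfolded protein response 0 passed at 24 h of DHT (camera adjusted p = 0.759), and of 13 p53 targets 2 fell, SESN1 (log2 -0.52) and CDKN1A (log2 -0.38), as adjusted over the list alone, with camera adjusted p = 0.11. By fry the p53 targets were lower at 24 h of DHT (adjusted p = 0.0152).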
